A study of Homo sapiens with 6 samples.

How the data were processed

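Total RNA of 3 parental and 3 sorafenib-resistant MV4-11 samples was extracted with TRIzol, amplified linearly by the Eberwine method and labelled with Cy3, per the labels' protocols. Each sample was hybridised to 1 array of a 60-mer human design with 62976 spots, whose probe positions refer to GRCh37, per the file headers. Groups came from the source name in the labels and replicate numbers from the titles. The headers place resistant replicate 1 on a second slide and scan and the other arrays on slide 1 and scan 1, whereas its title places it on the same slide as the others. Slide 2 holds only that array, so a fit with the slide as a block equals leaving it out.

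The authors deposited Agilent Feature Extraction 10.7.3.1 output for each array, per the file headers, in which each spot has an intensity, the processed signal, after background subtraction and detrending, with no normalization between arrays. The mean signal and local background of each spot are deposited intensities too, and the 0 or 1 marks for outlier, saturated and well above background spots, which are not measurements but other values, are deposited as Feature Extraction wrote them. The authors' value table holds log2 values. Set against the scanner files, each of its columns was the log2 processed signal, median over spots of a probe, minus the array's 75th percentile with control probes included, without centring per gene, and its columns had medians of -2.84, -2.64 and -2.73 for parental and -3.92, -3.77 and -3.54 for resistant replicates 1 to 3. The tool that made this table is not given in the sources used here.

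Spots marked as non-uniform or population outliers were removed, control spots were left out, spots of 1 probe were averaged, and log2 processed signals were scaled by subtracting each array's 75th percentile over non-control probes. No spot was saturated. Of 50599 probes, 28174 were named through their accession in a RefSeq gene table of assembly GRCh38.p14, used for names only, 2618 through their symbol and 620 through an older symbol; 17273 kept the name in the file and 1914 had no name and stayed out of gene tests. A probe was kept if it was well above background on every array of at least 1 group. 34016 named probes of 25040 genes were kept, 67 named probes having been left out for outlier spots. The probe with the highest mean over the 6 arrays stood for its gene. Where a probe was not well above background on any array of a group, the fold is given as at least N-fold: the mean of the brighter group against the mean of, per array, the higher of the dim probe's own value and the lowest value among probes well above background. The number of arrays limits the precision of all values.

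Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg over genes; called at an adjusted p under 0.05 and a log2 fold of at least 1). Gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry; a list needed 5 measured members. The mitochondrially encoded genes matched no symbol at first and were matched to the reference table through their synonyms after a first result without that list had been seen; its members were unchanged. The lists were: glycolysis; hypoxia-response genes other than glycolysis; nuclear-encoded oxidative phosphorylation; mitochondrially encoded genes; tricarboxylic acid cycle; pentose phosphate pathway; serine and one-carbon metabolism; ATF4 and integrated stress response; endoplasmic reticulum chaperones; cytosolic heat shock proteins; cholesterol synthesis and uptake; fatty acid synthesis; ERK pathway output; STAT5 targets; MYC targets; ribosomal proteins; DNA replication and G1/S; G2/M and mitosis; cell cycle inhibitors and p53 targets; BCL2 family; receptor tyrosine kinases and ligands; KMT2A-fusion and HOXA programme; ABC transporters and drug metabolism; NRF2 and antioxidant genes; interferon-stimulated genes; MHC class I presentation; MHC class II presentation; inflammatory cytokines and chemokines; monocyte and macrophage markers; granulocyte and primary granule markers; stem and progenitor markers; B-lineage markers; T and NK markers; erythroid and megakaryocyte markers; epithelial and fibroblast markers; adhesion and migration; autophagy and lysosome; replication-dependent histones. The called lists are described in detail, with 6 others chosen after seeing the data. Named genes followed a rule fixed before the data were examined. It took the 12 highest and 12 lowest folds among genes past the threshold whose groups did not overlap and whose probe was measured on all 6 arrays, without unnamed loci; the 5 genes with the largest bound in each direction; up to 4 members with the largest absolute fold in each list described; and 18 genes named whatever their change. Of the genes so taken, 5 were left out of the text and the plots, with none in their place. Arrays were summarised with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

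Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the authors' values, no filter on dim probes, only probes well above background on all 6 arrays, outlier spots kept, the mean over a gene's probes, an intensity trend with a robust prior, a replicate block, each array left out in turn, a 4-fold threshold, and for lists an estimated correlation and fry. Scaling on 8 E1A spike-in probes and the slide as a block were added after seeing the data. The fit was tested on simulated data of 25040 genes with the arrays' own spread, for resistant against parental: of 100 genes changed by a log2 of 3, 61% were called, and of 100 changed by 1.50, 4%, with 2 false calls. In simulated gene lists, 5 of 5 shifted lists and 0 others were called. Both simulations drew each gene independently, changed few genes and held no difference of brightness between the groups. Their rates therefore do not describe the fit or the list test on these data.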

Results

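Gene expression was measured in MV4-11 cells, a human acute leukemia line described by the submitters as biphenotypic B myelomonocytic, and in a derivative line, MV4-11-R, that survives sorafenib, an inhibitor of FLT3 and other kinases. The resistant line had been grown in sorafenib raised from 1 nM to 500 nM over 3 months and was kept in 500 nM. Total RNA from each line was hybridised to 3 one-colour Agilent arrays, giving 3 parental and 3 resistant arrays. The series' design text calls them biological replicates and does not say whether they came from separate cultures, so the p-values measure only the spread between these samples. Each array carried 50599 non-control probes.

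The arrays of the 2 groups differed in brightness before any scaling. The 75th percentile of the processed signal was 185 ± 62.1 (SD, n = 3) on the arrays labelled parental and 5025 ± 1328 (SD, n = 3) on the arrays labelled resistant. The share of probes well above background was 49.5% ± 5.94 (SD, n = 3) on the parental arrays and 72.2% ± 3.07 (SD, n = 3) on the resistant arrays. Each of these differences had an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow. The 8 E1A spike-in probes detect RNA added to the samples, at a step and in amounts not given in the sources used here. They had a geometric mean signal of 7597, 8161 and 19777 on parental replicates 1, 2 and 3, and of 7490, 6352 and 7100 on resistant replicates 1, 2 and 3. Across probes, which are not independent replicates, log2 signals correlated at r = 0.952 to 0.972 among parental arrays, 0.970 to 0.982 among resistant arrays and 0.502 to 0.543 between the groups. No pair of arrays in a group shared identical values.

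**Figure D1:**
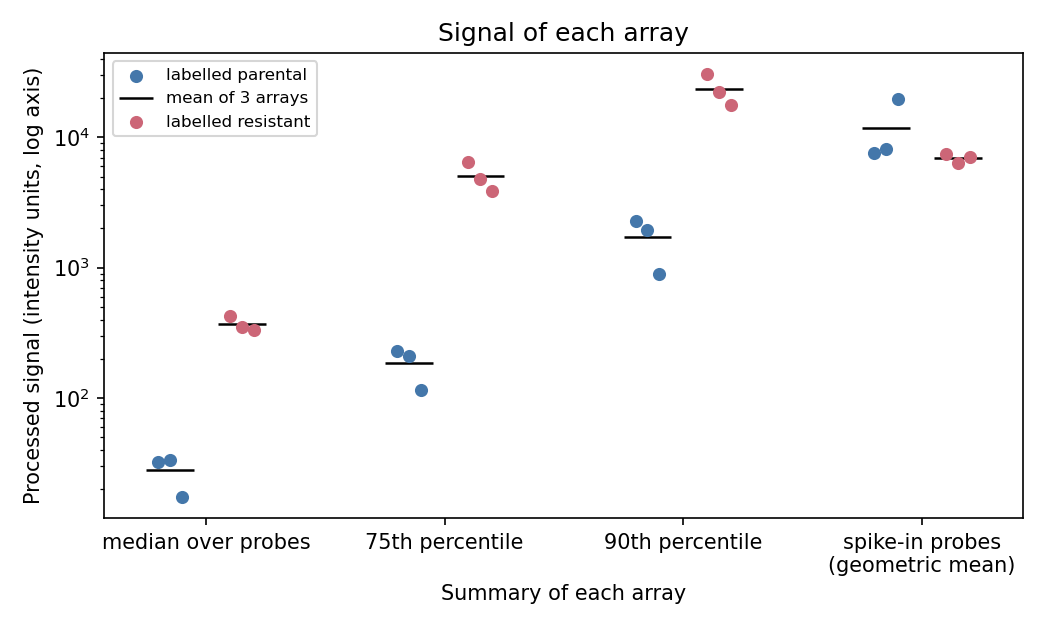
Processed signal of each array (intensity units, log axis) as the median, 75th and 90th percentile over non-control probes and as the geometric mean of the spike-in probes, with points for arrays and lines for means of 3 arrays. The resistant arrays have a higher 75th percentile, with a mean of 5025 against 185, while the spike-in probes do not.

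The comparison of resistant with parental arrays asks which transcripts differ between the line that survives sorafenib and its parent. The resistant line was kept in the drug, and no sorafenib is given for the parental samples. Exposure to the drug and resistance to it therefore cannot be told apart. FLT3, the receptor tyrosine kinase that sorafenib inhibits, was lower on the arrays labelled resistant, with a log2 fold of -11.85 ± 0.42 (SE, 3 against 3 arrays, limma adjusted p = 3.23e-07). GATA1, a transcription factor of erythroid and mast cell lineages, had a log2 fold of -13.34 ± 0.32, and ZEB1, a zinc finger repressor, one of -13.10 ± 0.30. On the higher side, the cancer-testis gene XAGE1A had a log2 fold of 7.20 ± 0.30, PCLAF, a PCNA-binding factor, one of 6.62 ± 0.29, and ARHGDIB one of 6.55 ± 0.34 (SE, limma adjusted p from 3.43e-07 to 4.79e-07). Mean parental signals were 44.4 for XAGE1A, 38.9 for PCLAF and 39.0 for ARHGDIB, where the lowest signal well above background was 19.3 to 29.7. On the resistant arrays GATA1 had 57.5 and ZEB1 70.1, where that lowest signal was 33.8 to 62.5. Background therefore limits the sizes of these folds. FLT3, GATA1, ZEB1, XAGE1A, PCLAF and ARHGDIB kept their direction under all 4 scalings compared. With spike-in scaling FLT3 had a log2 fold of -6.44, GATA1 of -7.92 and XAGE1A of 12.61. Median centring and spike-in scaling each add a positive constant to the fold of every probe. A positive fold or a large negative one therefore keeps its direction under both by construction. The probes of a gene often disagreed: of 6362 genes with several kept probes, 1859 (29.2%) had probes called in opposite directions. Most of the lower genes did not pass as lower under every scaling, and the arrays labelled parental carried little signal for many probes.

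In all, 7336 of 25040 genes tested were at least 2-fold higher on the resistant arrays and 13915 at least 2-fold lower at an adjusted p under 0.05, and 21583 passed the adjusted p at any fold. This split followed the filter and the scaling. With only probes well above background on all 6 arrays, 1719 of 14901 genes were higher and 11308 lower, so that the share of higher genes went from 34.5% to 13.2%, and without the filter 23106 genes were lower. With each array scaled on its spike-in probes, an alternative chosen after seeing the data that assumes an equal amount of spike-in RNA on every array, 16729 genes were higher and 443 lower, and the share of higher genes was 97.4%. The median log2 fold of all genes was -1.86 with 75th-percentile scaling, -0.83 with quantile normalization, -0.86 with median centring and 3.55 with spike-in scaling. Under all 4 scalings, 7502 genes passed the adjusted p as higher and 443 as lower, while 5775 passed it in opposite directions under different scalings. Leaving parental replicate 3, whose spike-in probes were the brightest, out of the spike-in scaling raised the number of lower genes from 443 to 1531. Of the 7502 genes higher throughout, 3953 had no probe well above background on any parental array.

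Of the 12 highest folds among genes measured on all 6 arrays, the 11 named here ranged from 6.13 for RPS28 to 7.20 for XAGE1A. They included the mitochondrially encoded ATP6, the inflammasome adaptor PYCARD (6.30 ± 0.33), the cytidine deaminase APOBEC3B (6.27 ± 0.39), the purine salvage enzyme PNP (6.21 ± 0.31), DBI, GTF3A, and the ribosomal protein genes RPS26 and RPS28. The 12 lowest ranged from -13.34 for GATA1 to -10.69 for TAGLN3. Among them were the aldose reductase gene AKR1B1 (-12.58 ± 0.40), the Wnt-related receptor gene LGR4 (-11.89 ± 0.30), the lymphoid transcription factor IKZF2 (-10.80 ± 0.38), the vesicular monoamine transporter SLC18A2 (-10.69 ± 0.55), PAOX, TCEAL9, RRAS2 and the small nucleolar RNA SNORD62A. These 23 genes kept their direction under the 4 scalings, which folds this large do by construction under median centring and spike-in scaling. Genes with no probe well above background on one group have only a bound, which is one on probe signal. It bounds expression only if the probe reads its transcript in both groups, which was not tested gene by gene. The largest bounds on the higher side were those of ILF2 (at least 223-fold), the leukocyte actin-bundling gene LCP1 (at least 215-fold), NBPF10 (at least 204-fold), GPX4 (at least 200.1-fold) and the chaperonin subunit CCT2 (at least 185-fold). With spike-in scaling these bounds ran from at least 7868-fold for CCT2 to at least 9497-fold for ILF2. Those of ILF2 and NBPF10 are by their brightest probe, and each had another kept probe that was not called. On the lower side they were those of PLXDC2 (at least 11343-fold), the Wnt co-receptor LRP6 (at least 11139-fold), eosinophil peroxidase EPX (at least 8239-fold), the endothelial receptor TIE1 (at least 5365-fold) and RBPMS2 (at least 4708-fold), which with spike-in scaling were at least 111-fold to 266-fold.

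**Figure D2:**
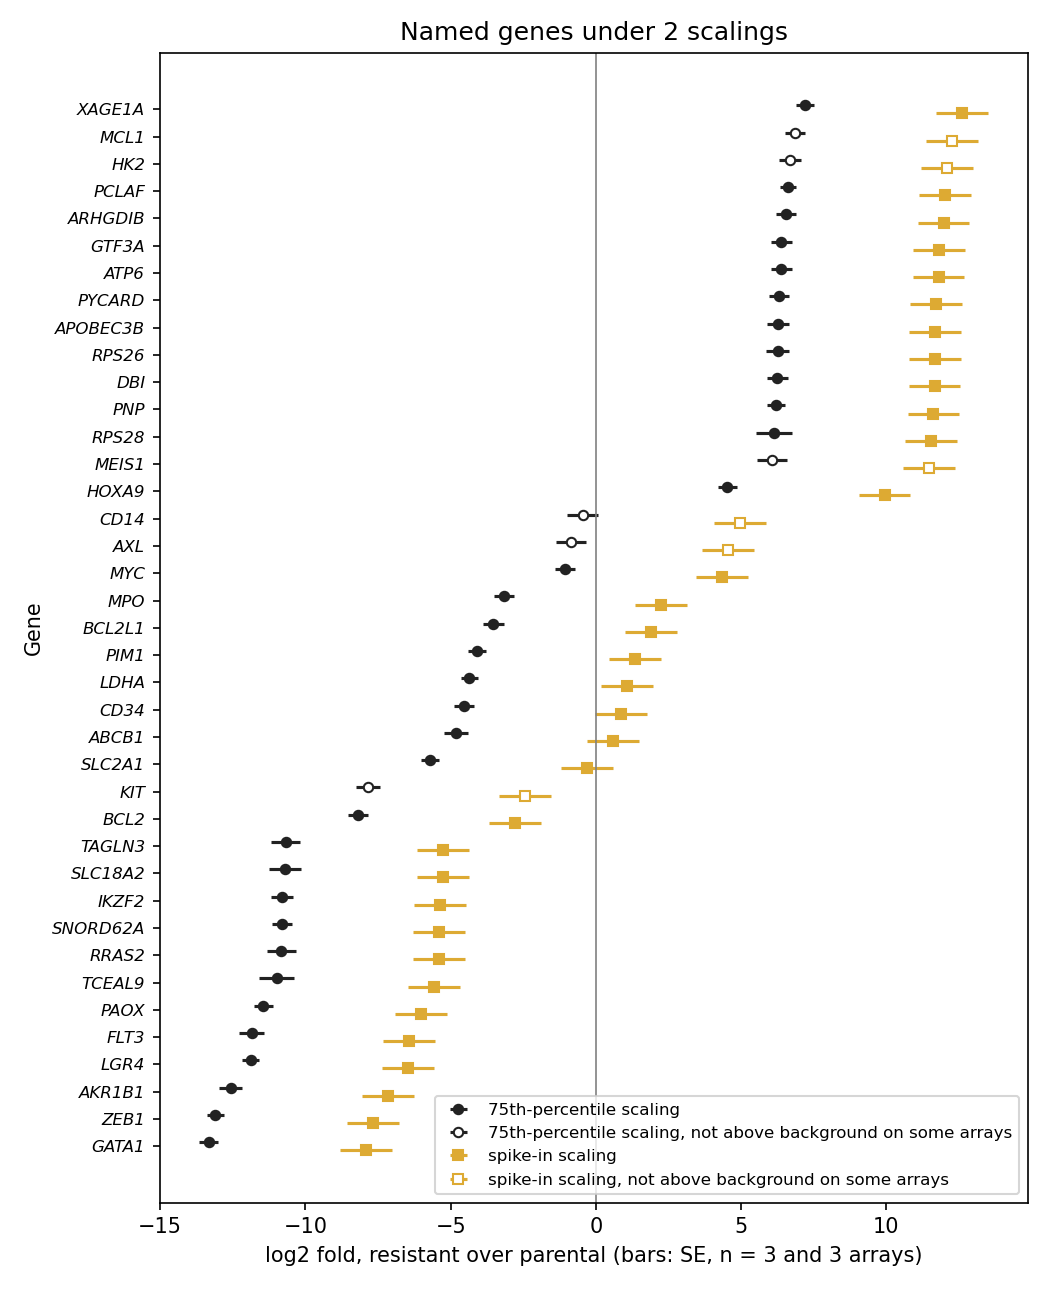
Log2 fold of 23 of the 24 genes with the largest folds and of the genes named whatever their change, with 75th-percentile scaling (circles) and spike-in scaling (squares), with bars for SE over 3 and 3 arrays and open symbols for probes not well above background on every array, whose fitted folds are no measured sizes. MYC is at -1.06 in the first and 4.35 in the second.

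Of all 25040 genes tested, 7506 passed the adjusted p as higher and 14077 as lower, against 16729 and 443 with spike-in scaling. Counts within a list that lie near these shares are no result about its members. Of the receptor tyrosine kinases and their ligands, 4 of 18 measured members rose and 11 fell, against 10 and 3 with spike-in scaling. Of the 11, 10 fell at least 2-fold. FLT3 and the stem cell factor receptor KIT were lower under all 4 scalings. KIT had a log2 fold of -7.85 ± 0.42, with its brightest probe well above background on 1 of the 3 resistant arrays. MERTK was at least 25.8-fold higher by its brightest probe, which was well above background on no parental array, and its second probe was called lower. The probe of AXL was well above background on all 3 resistant arrays and on no parental array, so its fold has no measured size, and it did not pass the test (limma adjusted p = 0.138). It passed as higher with spike-in scaling but as lower without resistant replicate 3, where the fitted log2 fold of AXL was -1.27. The list as a whole was not called by camera (adjusted p = 0.525, adjusted p = 0.709 with an estimated correlation). Its median lay above that of all genes while the direction of the test was down, and 3 of its members had no probe well above background on a parental array.

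In the BCL2 family, 7 of 16 measured members rose and 8 fell, against 13 and 1 with spike-in scaling; 7 of the 8 fell at least 2-fold, and camera did not call the list (adjusted p = 0.326, adjusted p = 0.543 with an estimated correlation). BCL2 had a log2 fold of -8.20 ± 0.34 by its brightest probe, negative under all 4 scalings, while its second probe was called higher. MCL1 was at least 29.8-fold higher and BCL2A1 at least 77.2-fold higher, and the proapoptotic BAK1 was at least 29.0-fold higher. Each had no probe well above background on a parental array, so these are bounds on probe signal only. BCL2L1 had a log2 fold of -3.53 ± 0.35, which became 1.88 with spike-in scaling. The STAT5 target PIM1 went from -4.08 ± 0.31 to 1.33, the drug efflux pump ABCB1 from -4.83 ± 0.40 to 0.59, and MYC from -1.06 ± 0.35 to 4.35 (1.17 with quantile normalization). Without resistant replicate 2 the log2 fold of MYC was -0.93, under the 2-fold threshold, and MYC no longer passed the adjusted p. ABCG2, another drug efflux pump, was not well above background on any array.

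Among genes of the KMT2A-fusion and HOXA programme, 10 of 20 measured members rose and 7 fell, against 18 and 1 with spike-in scaling (adjusted p = 0.0586 by camera, adjusted p = 0.252 with an estimated correlation). At 2-fold or more 9 rose and 7 fell. The list was called upward with normexp (adjusted p = 0.00475), no filter (0.00222), the mean over probes (0.0111) and spike-in scaling (0.0389) and without parental replicate 2 (0.0490). HOXA9, a homeobox gene of this programme, had a log2 fold of 4.52 ± 0.33 and was higher under all 4 scalings. CDK6 was at least 89.7-fold and SATB1 at least 86.5-fold higher. MEIS1, the partner of HOXA9, had a log2 fold of 6.05 ± 0.52 by its brightest probe, which was well above background on 1 of the 3 parental arrays; its other probes were both called lower. The member that fell with spike-in scaling was BCL2. No probe was well above background on a parental array for 5 members.

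In the gene lists, the counts at an adjusted p under 0.05 were also the counts at 2-fold or more and the counts adjusted over the list alone, for the lists described here except where another value is given. All 13 mitochondrially encoded genes were measured, and 12 rose and 0 fell, against 13 and 0 with spike-in scaling (camera adjusted p = 8.90e-05, adjusted p = 0.252 with an estimated correlation). Only ND1 had no probe well above background on any parental array. That complex I subunit was at least 123-fold higher, and ND4 had a log2 fold of 7.69 ± 0.46 by its brightest probe, well above background on 2 of the 3 parental arrays, and of 5.39 by its second probe. Mean parental signals were 14.8 for ND1, 18.8 for ND3, 29.1 for ND4 and 53.1 for the mitochondrially encoded COX2. On the resistant arrays they ran from 74710 for ND3 to 180174 for COX2. Whether the parental hybridisations read these transcripts was not tested, so the rise cannot be taken as a change of expression. For glycolysis, 14 of 25 measured members rose and 10 fell, against 18 and 0 with spike-in scaling. Camera did not call it with 75th-percentile scaling (adjusted p = 0.0543, adjusted p = 0.252 with an estimated correlation; 6 members had no probe well above background on a parental array). It was called upward with normexp (adjusted p = 0.0120), quantile normalization (0.0144), no filter (0.00108), the mean over probes (0.00496), a replicate block (0.0468) and spike-in scaling (0.0114) and without parental replicate 1 (0.0468), parental replicate 2 (0.0421), resistant replicate 2 (0.0458) and resistant replicate 3 (0.0498). PDK1, which restrains pyruvate dehydrogenase, was at least 124-fold and hexokinase HK1 at least 31.3-fold higher. HK2 had a log2 fold of 6.68 ± 0.38, LDHB of 7.22 ± 0.36 and GPI of 7.85 ± 0.59, each with its brightest probe well above background on 1 of the 3 parental arrays. The second probe of HK2 was not called. The glucose transporter SLC2A1 had a log2 fold of -5.71 ± 0.31 and -0.29 with spike-in scaling. LDHA went from -4.35 ± 0.30 to 1.06 under that scaling, with its 2 probes called in opposite directions. In the tricarboxylic acid cycle, 12 of 22 measured members rose and 8 fell, against 18 and 0 with spike-in scaling (camera adjusted p = 0.0398, adjusted p = 0.252 with an estimated correlation), and 3 had no probe well above background on a parental array. The list was not called with median centring (adjusted p = 0.0538) or only probes above background on all 6 arrays (0.475) or without parental replicate 3 (0.0660). SUCLG1, a succinyl-CoA ligase subunit, was at least 67.2-fold higher, and the malate dehydrogenase MDH2 had a log2 fold of 6.64 ± 0.29, with the probe well above background on 2 of the 3 parental arrays. In the pentose phosphate pathway, 7 of 10 measured members rose and 2 fell, against 9 and 0 with spike-in scaling (camera adjusted p = 0.0225, adjusted p = 0.252 with an estimated correlation), and 2 had no probe well above background on a parental array. TALDO1, the transaldolase, had a log2 fold of 4.83 ± 0.39, and PRPS2 was at least 17.9-fold higher.

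In serine and one-carbon metabolism, 9 of 15 measured members rose and 5 fell, against 14 and 0 with spike-in scaling (camera adjusted p = 0.0339, adjusted p = 0.543 with an estimated correlation), and 5 had no probe well above background on a parental array. This call was not kept with median centring (adjusted p = 0.0533) or only probes above background on all 6 arrays (0.530). Thymidylate synthase TYMS was at least 118-fold and the mitochondrial folate enzyme MTHFD2 at least 73.2-fold higher. Among genes of cholesterol synthesis and uptake, 15 of 21 measured members rose and 5 fell, against 19 and 0 with spike-in scaling (camera adjusted p = 0.00125, adjusted p = 0.252 with an estimated correlation), and 7 had no probe well above background on a parental array. That call was not kept with only probes above background on all 6 arrays (adjusted p = 0.0756). The squalene epoxidase SQLE was at least 38.7-fold and CYP51A1 at least 29.4-fold higher. For NRF2 and antioxidant genes, 12 of 22 measured members rose and 7 fell, against 18 and 0 with spike-in scaling (camera adjusted p = 0.0398, adjusted p = 0.565 with an estimated correlation), and 8 had no probe well above background on a parental array. The call was not kept with median centring (adjusted p = 0.0538) or only probes above background on all 6 arrays (0.475). Catalase CAT was at least 132-fold, the lipid peroxide reductase GPX4 at least 200.1-fold and the NRF2 inhibitor KEAP1 at least 39.7-fold higher. In the autophagy and lysosome list, 11 of 20 measured members rose and 6 fell, against 17 and 0 with spike-in scaling (camera adjusted p = 0.0295, adjusted p = 0.252 with an estimated correlation), and 3 had no probe well above background on a parental array. The lysosomal proteases CTSB (at least 49.8-fold) and CTSD (log2 fold 5.99 ± 0.39) and the membrane protein LAMP2 (at least 74.7-fold) were higher.

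Of the genes of DNA replication and the G1/S transition, 16 of 24 measured members rose and 5 fell, against 21 and 0 with spike-in scaling (camera adjusted p = 0.00289, adjusted p = 0.252 with an estimated correlation), and 6 had no probe well above background on a parental array. MCM3, a subunit of the replicative helicase, was at least 140.1-fold, MCM6 at least 123-fold and GINS1 at least 63.0-fold higher. Of those of G2/M and mitosis, 14 of 22 measured members rose and 6 fell, against 19 and 0 with spike-in scaling (camera adjusted p = 0.00231, adjusted p = 0.252 with an estimated correlation), and 7 had no probe well above background on a parental array. The mitotic kinase AURKA was at least 99.8-fold, the topoisomerase TOP2A at least 96.0-fold and NUSAP1 at least 80.2-fold higher, and CCNB2 had a log2 fold of 7.68 ± 0.48, with the probe well above background on 1 of the 3 parental arrays.

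Among interferon-stimulated genes, 15 of 23 measured members rose and 4 fell, against 23 and 0 with spike-in scaling (camera adjusted p = 0.00497, adjusted p = 0.584 with an estimated correlation), and 7 had no probe well above background on a parental array. The tetherin gene BST2 was at least 138-fold by its brightest probe, STAT2 at least 40.1-fold and IFIT1 at least 10.8-fold higher. For MHC class I presentation, 8 of 15 measured members rose and 3 fell, against 15 and 0 with spike-in scaling (camera adjusted p = 0.0295, adjusted p = 0.252 with an estimated correlation), and 2 had no probe well above background on a parental array. The list was not called with only probes above background on all 6 arrays (adjusted p = 0.216). HLA-B was at least 109-fold by its brightest probe and the peptide transporter TAP1 at least 49.6-fold higher. Among inflammatory cytokines and chemokines, 11 of 20 measured members rose and 3 fell, against 17 and 0 with spike-in scaling (camera adjusted p = 0.0254, adjusted p = 0.397 with an estimated correlation), and 7 had no probe well above background on a parental array. This call was not kept with normexp (adjusted p = 0.0513) or only probes above background on all 6 arrays (0.0654). Of the members that rose, 10 did so at least 2-fold. The chemokine CCL2 was at least 56.0-fold higher and CCL5 had a log2 fold of 7.19 ± 0.36, with the probe well above background on 2 of the 3 parental arrays. CCL4 had -5.40 ± 0.36, and 0.010 with spike-in scaling. Of the granulocyte and primary granule markers, 11 of 16 measured members rose and 2 fell, against 16 and 0 with spike-in scaling (camera adjusted p = 0.00231, adjusted p = 0.252 with an estimated correlation), and 4 had no probe well above background on a parental array. MS4A3 was at least 44.1-fold and FUT4 at least 37.2-fold higher, and proteinase 3, PRTN3, had a log2 fold of 6.76 ± 0.57, with the probe well above background on 1 of the 3 parental arrays. Myeloperoxidase, MPO, had -3.16 ± 0.33, and 2.25 with spike-in scaling. For adhesion and migration, 15 of 22 measured members rose and 4 fell, against 22 and 0 with spike-in scaling (camera adjusted p = 0.00114, adjusted p = 0.252 with an estimated correlation), and 4 had no probe well above background on a parental array. The hyaluronan receptor CD44 was at least 35.0-fold by its brightest probe, its second probe not being called, and the integrin ITGAM at least 8.53-fold higher, and CD47, an inhibitory ligand for phagocytes, had a log2 fold of 5.28 ± 0.38. Of the surface markers named whatever their change, CD34 had a log2 fold of -4.54 ± 0.33 (0.87 with spike-in scaling), and CD14 of -0.45 ± 0.53 (limma adjusted p = 0.433; 4.96 with spike-in scaling), with its probe well above background on 2 of the 3 parental arrays.

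**Figure D3:**
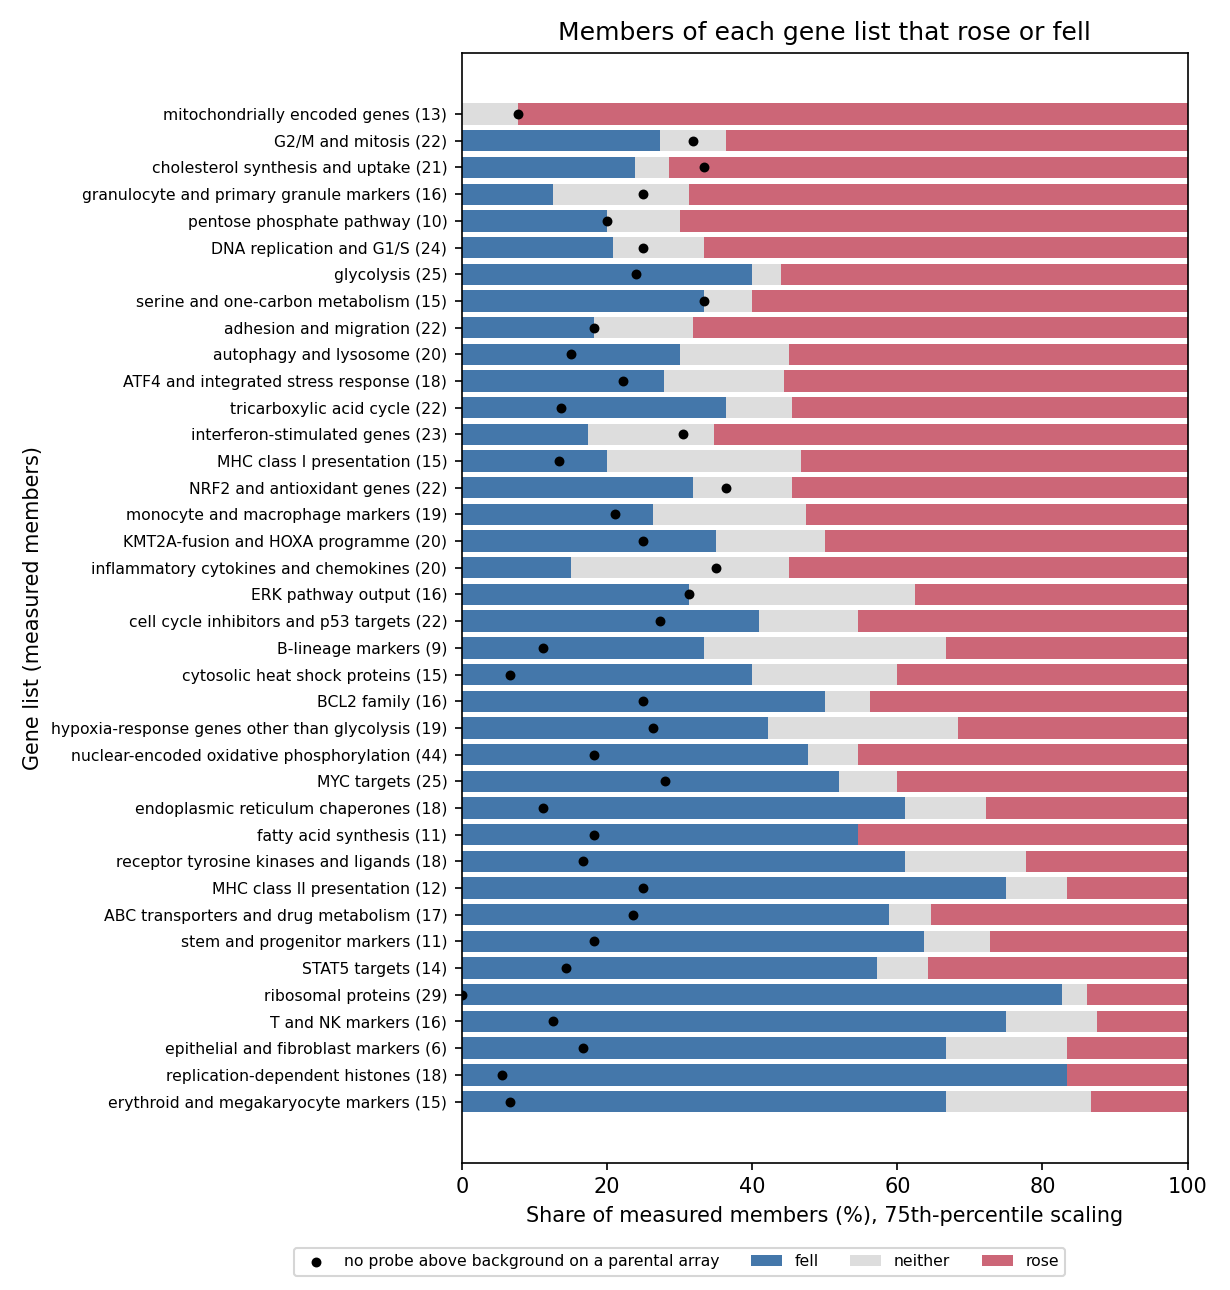
Share of the measured members of each gene list that fell, did neither or rose with 75th-percentile scaling, ordered by the list's median log2 fold, with points for the share of members with no probe well above background on a parental array. Of the mitochondrially encoded genes, 12 of 13 rose, and 13 with spike-in scaling, while of the ribosomal proteins 24 of 29 fell, and 0 with spike-in scaling.

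Of the ribosomal protein genes, 4 of 29 measured members rose and 24 fell, against 18 and 0 with spike-in scaling (camera adjusted p = 0.0586, adjusted p = 0.706 with an estimated correlation). This list was called downward with an intensity trend and robust prior (adjusted p = 0.0312) and without parental replicate 2 (0.0490). Every measured member had its brightest probe well above background on all 3 parental arrays. RPL8 had a log2 fold of -4.57 ± 0.39, RPS3 -4.56 ± 0.36 and RPS20 -4.45 ± 0.38, which became 0.85, 0.85 and 0.97 with spike-in scaling; the second probe of RPS20 was called higher. Over all 179 kept probes of 83 ribosomal protein genes, the unscaled log2 difference of parental minus resistant had a median of -3.02 and quartiles of -8.55 and -1.07. Of these probes, 146 were well above background on all 3 parental arrays and 21 on none. The extremes were -13.69 for a probe of RPS3A and 3.26 for a probe of RPL3L. The first was above background on no parental array and the second on no resistant array, so neither is a measured size. Of the replication-dependent histones, 3 of 18 measured members rose and 15 fell, against 7 and 2 with spike-in scaling (camera adjusted p = 0.0586, adjusted p = 0.397 with an estimated correlation), and 1 had no probe well above background on a parental array. They were called downward with an intensity trend and robust prior (adjusted p = 0.0427) and spike-in scaling (0.0277). H2AC4 had a log2 fold of -10.25 ± 0.37 and H4C8 of -7.66 ± 0.46, both lower under all 4 scalings.

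**Figure D4:**
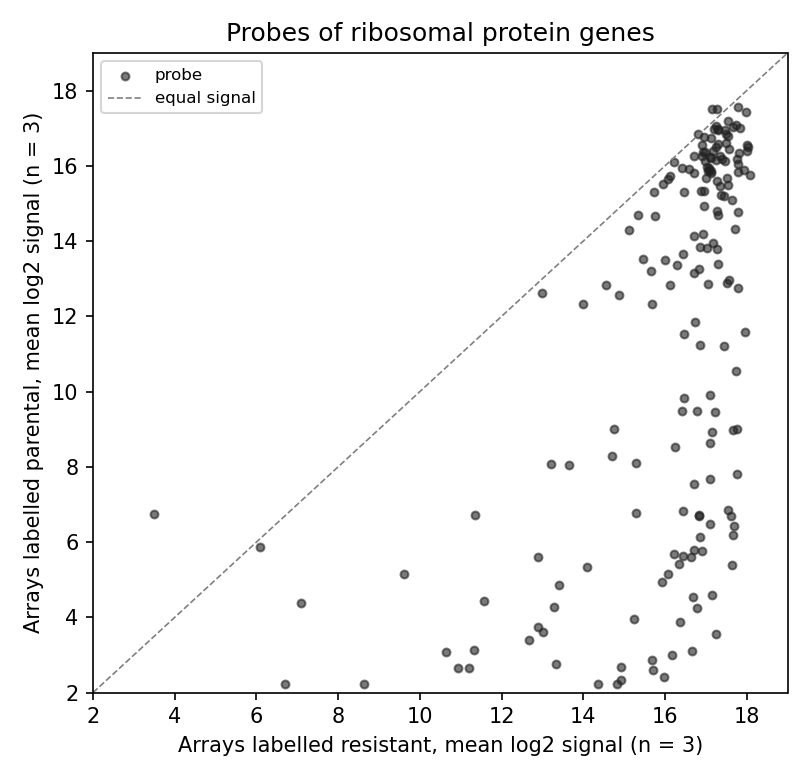
Mean log2 signal of each kept probe of a ribosomal protein gene on the arrays labelled parental (vertical axis, n = 3) against those labelled resistant (horizontal axis, n = 3), before scaling; the dashed line marks equal signal. Points spread downward from the line, with a median difference of -3.02 and a lowest of -13.69, for a probe above background on no parental array.

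Folds are from limma on log2 signal, adjusted over genes by Benjamini-Hochberg, and list tests are camera with a preset inter-gene correlation of 0.01, adjusted over 38 lists, of which 14 were called, all upward. An intensity trend with a robust prior called 16 lists, with ribosomal proteins and histones downward, and spike-in scaling 19, with histones and erythroid and megakaryocyte markers downward. With an estimated correlation camera called 0 lists, 4 having an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 34. The groups did not overlap for 21714 genes (86.7%). The share of 10% that chance gives does not apply here, because the filter that kept the genes used the groups and all genes share the same arrays.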

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

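The tests of label yield, of RNA breakage, of a change of expression and of other splits were chosen after the result was seen. The idea of another species' RNA came from these data, and its test was set before its share was computed, on genes not looked at before. Some of the probes without a gene name, which entered no comparison, carried signal on 1 group alone. 255 of 1914 unnamed probes were well above background on all 3 resistant arrays and on no parental array, and 16 the other way round. Among named probes the shares were 19.4% and 1.01%, against 13.3% and 0.836% of unnamed probes. Such signal was thus not particular to unnamed probes.

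The arrays labelled parental stood apart from those labelled resistant on most probes, 21251 of 25040 genes being called. The tables argue against a lower yield of label and against broken RNA as the whole cause. They do not decide on a change of expression. A lower yield of label would dim all RNA alike, but over 179 ribosomal protein probes the unscaled log2 differences had an interquartile range of 7.48. Of these probes, 146 were well above background on all 3 parental arrays, and background limits the losses of the rest. Broken RNA primed from its 3' end would cost the 5' probes of a transcript most. Within 3553 transcripts, however, the log2 difference of parental minus resistant was higher at the most 5' probe than at the most 3' probe, by a median of 1.83 (95% bootstrap interval 1.62 to 2.02). That interval measures the spread between transcripts on the same arrays, which are not independent replicates, and not the spread between samples. A change of expression between resistant and parental human cells is the biological explanation that the design offers. It would move the probes of a transcript together if each probe read that transcript alone. Signal from background or other RNA can shrink the loss of a probe, also of one that stays above background. In 51.6% of 1245 transcripts with several bright probes, another probe lost at least 4 log2 units more than one that was well above background on all 3 parental arrays. Among 644 transcripts with several bright probes above background on all 6 arrays, 28.6% held such a gap. The share that a true change of expression would give was not measured, and a switch between isoforms was not tested. These shares therefore show that probes of a transcript often disagreed, without deciding on this explanation. Changes of single genes between the lines stay open.

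RNA of another species on the arrays labelled parental, from a mixed-up or mislabelled sample, is a candidate explanation that stays open. Of 113 probes of gene families expanded in primates that were well above background on all 3 resistant arrays, 45.1% were so on all 3 parental arrays. In 10000 random sets of probes of like brightness the median was 56.6% and the 5th percentile 48.7%. Probes of a gene are not independent, which these sets do not allow for. Probes of deeply conserved genes, at 78.5%, lay inside their random range of 64.6% to 79.7% (5th to 95th percentile). No other genome was matched to the probes, and other faults of the parental hybridisations were not tested. With these open, the differences reported here cannot be assigned to sorafenib resistance.

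The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 21251 genes at limma's adjusted p and 2-fold threshold and the highest of the other splits 0, so that 1 of the 10 splits, the real one, gave as many. Each other split mixes arrays of both groups, so the difference between the groups enters its spread and keeps genes from being called. The 0 of those splits is therefore no reference for what chance gives.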

How the results depend on the processing

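Spike-in scaling and the slide block were chosen after seeing the data; the other alternatives before. The counts of genes higher (7336), lower (13915) and past the adjusted p (21583) and of called lists (14) stayed within 1.5 times under normexp, quantile normalization, median centring, the authors' values, kept outlier spots, the mean over probes, the trend and robust prior and the slide block. Leaving out 1 array at a time gave 7077 to 7412 higher, 13675 to 13978 lower, 20808 to 21819 past the adjusted p and 13 to 18 lists. A 4-fold threshold left 6034 and 12258. With only probes well above background on all 6 arrays, which leaves 14901 genes, 1719 were higher and 11308 lower, and 13360 passed the adjusted p. Without the filter, which adds genes measured on neither group, 23106 were lower. Spike-in scaling gave 16729 higher and 443 lower; it called 5605 of the 21251 genes the opposite way, and its SE of 0.89 comes from the spike-in probes' spread, which all genes share, so that its p-values are too small. Without parental replicate 3 it gave 16953 and 1531. Fry, which does not compare a list with other genes, called 34 lists and camera with an estimated correlation 0. Median centring called 11 lists, without those of the tricarboxylic acid cycle, serine metabolism and NRF2. The filter on all 6 arrays called 12, without these 3, cholesterol, MHC class I and inflammatory cytokines but with oxidative phosphorylation, ATF4, heat shock and monocyte lists. Normexp called 17, without inflammatory cytokines. Quantile normalization called 16, the mean over probes 17, no filter 21 and the trend and robust prior 16, the last with ribosomal proteins and histones downward. Spike-in scaling called 19, with histones and erythroid and megakaryocyte markers downward. The adjusted p of each such list stands beside it. A reversal was counted only where the list or gene passed under the main setting or the alternative. Counted so, no list's median relative to that of all genes reversed. By the same count, 21 of 38 lists and 99 of 118 named genes kept direction and call under each alternative that measured them. Sign changes of lists or genes that passed under neither setting were not counted. The sign turned with spike-in scaling for CCL4 (0.010), RPL8 (0.85), RPS3 (0.85), RPS20 (0.97), AXL (4.56), BCL2L1 (1.88), PIM1 (1.33), MYC (4.35), ABCB1 (0.59), LDHA (1.06), CD34 (0.87), CD14 (4.96) and MPO (2.25), because that scaling adds a constant to every fold. Of these genes, CCL4, RPL8, RPS3, RPS20, BCL2L1, PIM1, ABCB1, LDHA and CD34 did not pass the adjusted p with spike-in scaling. Their sign turned without a call in the other direction. AXL and CD14, not past the test, also changed sign with quantile normalization (0.79 and 0.34) and median centring (0.15 and 0.55), and CD14 without resistant replicate 3 (0.11). Among called folds it turned with quantile normalization for MERTK (-3.28, by another probe) and MYC (1.17; the cause was not tested), with the mean over probes, which went opposite ways, for LDHA (0.87), and with probes measured on all 6 arrays, which takes another probe of the gene, for SUCLG2 (-3.35), MERTK (-3.81) and MEIS1 (-3.02). Signal over background limits the parental side, where 49.5% of probes were well above it.

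Arrays of the same replicate number deviated together little (r = 0.117, -0.0126 and 0.0572), so the numbers do not pair them. With the replicate block, 7347 genes were higher, 13977 lower and 21630 past the adjusted p, and 15 lists were called.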

Other observations

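Camera on the kept probes of all 6 arrays with 75th-percentile scaling did not call the lists in this part. Spike-in scaling was chosen after seeing the data. Of all 25040 genes, 7506 rose and 14077 fell, against 16729 and 443 with spike-in scaling. List counts near these shares are no result about the members. Of 19 monocyte and macrophage markers, 10 rose and 5 fell, against 16 and 0 with spike-in scaling (camera adjusted p = 0.102, and 0.662 with an estimated correlation), and 4 had no probe well above background on a parental array. In that list 9 rose at least 2-fold and 9 rose when adjusted over the list alone, and it was called upward with no filter (adjusted p = 0.0229) and only probes above background on all 6 arrays (0.0435) and without resistant replicate 3 (0.0254). Of 11 stem and progenitor markers, 3 rose and 7 fell, against 6 and 2 with spike-in scaling (camera adjusted p = 0.496, and 0.709 with an estimated correlation), and 2 had no probe well above background on a parental array. Among 9 B-lineage markers, 3 rose and 3 fell, against 7 and 0 with spike-in scaling (camera adjusted p = 0.543, and 0.706 with an estimated correlation), and 1 had no probe well above background on a parental array. Of 16 T and NK markers, 2 rose and 12 fell, against 8 and 0 with spike-in scaling (camera adjusted p = 0.271, and 0.656 with an estimated correlation), and 2 had no probe well above background on a parental array. Among 15 erythroid and megakaryocyte markers, 2 rose and 10 fell, against 6 and 1 with spike-in scaling (camera adjusted p = 0.215, and 0.565 with an estimated correlation), and 1 had no probe well above background on a parental array. These were called downward with spike-in scaling (adjusted p = 0.0389). Of 6 epithelial and fibroblast markers, 1 rose and 4 fell, against 3 and 0 with spike-in scaling (camera adjusted p = 0.525, and 0.706 with an estimated correlation), and 1 had no probe well above background on a parental array. Of 12 genes of MHC class II presentation, 2 rose and 9 fell, against 11 and 0 with spike-in scaling (camera adjusted p = 0.543, and 0.706 with an estimated correlation), and 3 had no probe well above background on a parental array. 443 genes were lower under all 4 scalings, and 1531 passed as lower with spike-in scaling when parental replicate 3 was left out. The 443 include from these lists GATA1, KIT and MECOM, a regulator of blood stem cells, of which MECOM was chosen after its values were seen. The brightest probe of MECOM was well above background on 0 of the 3 resistant arrays, and it was at least 3655-fold lower, and at least 85.8-fold with spike-in scaling.

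Of 16 genes of ERK pathway output, 6 rose and 5 fell, against 14 and 0 with spike-in scaling (camera adjusted p = 0.164, and 0.397 with an estimated correlation), and 5 had no probe well above background on a parental array. Adjusted over the list alone, 3 of them fell, and the list was called upward with no filter (adjusted p = 0.0316). Of 14 STAT5 targets, 5 rose and 8 fell, against 7 and 1 with spike-in scaling (camera adjusted p = 0.947, and 0.948 with an estimated correlation), and 2 had no probe well above background on a parental array. Among 25 MYC targets, 10 rose and 13 fell, against 17 and 0 with spike-in scaling (camera adjusted p = 0.442, and 0.673 with an estimated correlation), and 7 had no probe well above background on a parental array. Of 22 cell cycle inhibitors and p53 targets, 10 rose and 9 fell, against 16 and 0 with spike-in scaling (camera adjusted p = 0.271, and 0.543 with an estimated correlation), and 6 had no probe well above background on a parental array. This list was called upward with no filter (adjusted p = 0.0309). Of 17 genes of ABC transporters and drug metabolism, 6 rose and 10 fell, against 9 and 0 with spike-in scaling (camera adjusted p = 0.890, and 0.921 with an estimated correlation), and 4 had no probe well above background on a parental array. Of 44 nuclear-encoded oxidative phosphorylation genes, 20 rose and 21 fell, against 41 and 0 with spike-in scaling (camera adjusted p = 0.0586, and 0.397 with an estimated correlation), and 8 had no probe well above background on a parental array. At 2-fold or more 19 rose, and the list was called upward with normexp (adjusted p = 0.00168), quantile normalization (3.88e-05), no filter (8.73e-04), only probes above background on all 6 arrays (0.0411), the mean over probes (0.0179) and spike-in scaling (0.00130) and without parental replicate 1 (0.0468), parental replicate 2 (0.0471) and resistant replicate 2 (0.0458). Among 19 hypoxia-response genes other than glycolysis, 6 rose and 8 fell, against 14 and 0 with spike-in scaling (camera adjusted p = 0.479, and 0.622 with an estimated correlation), and 5 had no probe well above background on a parental array. Of 11 genes of fatty acid synthesis, 5 rose and 6 fell, against 7 and 0 with spike-in scaling (camera adjusted p = 0.447, and 0.706 with an estimated correlation), and 2 had no probe well above background on a parental array. Of 18 genes of the ATF4 and integrated stress response, 10 rose and 5 fell, against 15 and 0 with spike-in scaling (camera adjusted p = 0.0658, and 0.662 with an estimated correlation), and 4 had no probe well above background on a parental array. The ATF4 list was called upward with normexp (adjusted p = 0.0374), no filter (0.00320) and only probes above background on all 6 arrays (0.0206) and without resistant replicate 2 (0.0487). Of 18 endoplasmic reticulum chaperones, 5 rose and 11 fell, against 13 and 0 with spike-in scaling (camera adjusted p = 0.890, and 0.913 with an estimated correlation), and 2 had no probe well above background on a parental array. Among 15 cytosolic heat shock proteins, 6 rose and 6 fell, against 10 and 0 with spike-in scaling (camera adjusted p = 0.442, and 0.622 with an estimated correlation), and 1 had no probe well above background on a parental array. The heat shock list was called upward with only probes above background on all 6 arrays (adjusted p = 0.0411). With spike-in scaling, camera called 19 of 38 lists, 2 of them downward, the histones and the erythroid and megakaryocyte markers. The median and the test direction of the STAT5 target and receptor kinase lists differed in sign.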
